A study of Glycine soja and Glycine max with 13 samples.

How the data were processed

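RNA was measured in seeds of 6 cultivated and 7 wild soybean lines, 13 days after flowering, from plants grown in fields. Per the labels' protocols, libraries were made with a stranded mRNA kit from DNase-treated total RNA, and per the series' design text they were sequenced as read pairs. The submitters' processing notes list Trim Galore 0.3.3, TopHat2, SAMtools and edgeR, without their order or roles. The counting tool, the genome build and the annotation are not given in the sources used here. The deposited values are whole-number read counts per gene for 43517 features with soybean identifiers, not normalized by the authors as far as the values show, since they are whole and their sums differ between lines. All 13 sample columns were used, each matched to its line by the line name in the sample title, and each line was taken as cultivated or wild from its strain label.

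The files pair no identifier with a name, and of 59365 rows in the RefSeq gene table given for the organism (Glycine soja assembly ASM419377v2) 0 matched an identifier. Gene products, positions, lengths and GC content were therefore not used here, and any check of length or GC content would be void. Before the data were examined, 34 gene lists were fixed as word patterns on product descriptions, and 7 of them also held published identifiers. The other 27 lists could not be filled and were not tested. Names such as GmSWEET10a were attached to their identifiers when the lists were fixed, from identifiers known from the literature, with 19 size and domestication identifiers in all. It had been planned to keep an identifier only where its annotated product matched, and this could not be checked, so no name was checked against a table. How the authors' counting treated reads that match several genes is not given in the sources used here, so values of near-identical copies, such as storage protein genes, are uncertain. Whether the counting used the strand is not given either, so reads of overlapping and antisense genes may be mixed.

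Totals ran from 12.7 M to 26.0 M counts per line, and a floor of 3 counts stood for 0.115 to 0.237 CPM of these unscaled totals. Read pairs carry no molecular identifiers, so floors cover counting error only. Libraries were checked for duplicates with a chi-square of each pair over genes with at least 20 counts, and the lowest value per degree of freedom was 21.8, so every line was kept as its own replicate. A count of 0 in all lines was found for 2290 features. Tests ran on 31420 genes kept by the edgeR expression filter with the group given. Counts were scaled by TMM factors, and CPM values of genes in the text are on that scale, where 3 counts stood for 0.111 CPM in ys16 and 0.243 CPM in df3. The limits set by depth are on the unscaled totals.

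Cultivated and wild lines were compared with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with the group as the only term and Benjamini-Hochberg adjustment at 0.05. A second count took calls with an absolute log2 fold change of at least 1. Fold changes are cultivated over wild, and a standard error is the log2 fold change divided by the square root of the F statistic. Lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM at a preset correlation of 0.01, with an estimated correlation and with fry. Single values per line, correlations between lines and the spread between lines were tested by exact permutation over the 1716 splits of 13 lines, and relations across 13 lines by 100000 permutations (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3). Figures were drawn with matplotlib 3.10.9. Log2 CPM used a prior count of 2.

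The rule for named genes was fixed before the data were examined. It took up to 6 genes per direction with an edgeR adjusted p under 0.05, at least 10 mean CPM in the higher group and no overlap between groups, the 3 members with the smallest p of each list that passed camera after adjustment or had at least 20% and at least 2 of its tested members past the gene test, every measured size or domestication gene, and the most abundant member of the storage protein, flavonoid and photosynthesis lists. The first part was met by 9 genes, 4 higher and 5 lower in cultivated seeds. Because nothing pairs them with names, only the 2 with the largest fold change in each direction are printed. No list met its part of the rule, which did not use fry.

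The alternatives fixed before the data were examined were RLE and upper-quartile factors, no filter, a stricter filter (at least 1 CPM in 6 lines and a mean of at least 5 CPM), DESeq2 1.42.0, limma voom with quality weights, 1 surrogate variable from sva 3.50.0, and leaving out each line. The storage protein score as a term in the model, the removal of the 8 most abundant features and the removal of ys29 and ys34 together were added after seeing the data. The edgeR test was tested on simulated data drawn from the means and library sizes of these lines, with 31079 genes kept. It recovered 36.8% of 68 genes changed 2-fold, 86.4% of 66 changed 4-fold and 100% of 65 changed 16-fold, and 11 of its 158 calls were unchanged genes. The changed genes were taken only from those above a limit on the mean count. Each gene was drawn independently of the others, so these shares do not cover variation that many genes share between the real lines. The search for single lines far from their group covered the library measures, the size, domestication and storage genes and the 9 genes of the first part of the rule, and its values are given only for genes printed in the text, a choice made after its first result was seen.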

Results

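Seed transcripts were measured by strand-specific RNA sequencing in 13 soybean lines, 13 days after flowering. Cultivated soybean (Glycine max) was represented by 6 lines, named df12, df14, df17, df36, df3 and df43. Wild soybean (Glycine soja), the relative from which the crop was domesticated, was represented by 7 lines, named ys16, ys17, ys1, ys23, ys26, ys29 and ys34. The question set by the title of the series was which genes relate to seed weight, which is far greater in the crop than in its wild relative. Each sample was a different line, so the spread within a group was the spread between lines. The labels do not say how many plants or seeds went into a sample, and none of them names a batch. The read counts of a line summed to between 12.7 M and 26.0 M (M, mega), with a median of 16.6 M. They averaged 17.9 ± 4.67 M in cultivated lines (SD, n = 6) and 17.4 ± 3.05 M in wild lines (SD, n = 7), a difference within the spread between lines (exact permutation test, two-sided p = 0.789). At these depths 3 counts, the most that a count of 0 allows, stood for 0.115 to 0.237 CPM (counts scaled to 1 M per line) of the unscaled totals, a limit that covers counting error only. The CPM of genes below are also scaled by TMM factors, where 3 counts stood for 0.111 CPM in ys16 and 0.243 CPM in df3. The 8 most abundant features took 22.9 ± 5.47% of counts in cultivated lines (SD, n = 6) and 25.5 ± 7.11% in wild lines (SD, n = 7; exact permutation test, two-sided p = 0.498). Their share was highest in ys34 (39.2%), df3 (32.4%) and ys29 (30.7%).

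Of 31420 tested genes, 14 were called different between cultivated and wild seeds by edgeR, 8 of them higher and 6 lower in the cultivated lines, and all 14 by at least 2-fold. Glyma.02G270400 was 4.10-fold higher in cultivated seeds, at 18.2 ± 5.72 CPM (SD, n = 6) against 4.42 ± 0.809 CPM in wild seeds (SD, n = 7). Its log2 fold change was 2.04 with a standard error of 0.202 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00141). Glyma.08G012900 was 4.18-fold higher, at 14.9 ± 4.11 CPM against 3.55 ± 1.52 CPM (log2 fold change 2.07, SE 0.312, edgeR adjusted p = 0.0251). In the other direction, Glyma.11G134300 was 14.1-fold lower in cultivated seeds, at 1.33 ± 0.734 CPM against 18.4 ± 11.7 CPM (log2 fold change -3.82, SE 0.554, edgeR adjusted p = 0.0178). Glyma.05G085600 was 9.86-fold lower, at 1.77 ± 0.205 CPM against 17.5 ± 7.11 CPM (log2 fold change -3.30, SE 0.358, edgeR adjusted p = 0.00159), although wild line ys1 held only 3.20 CPM of it. For each of these 4 genes all lines of one group lay above all lines of the other, but the rule for naming genes required this. It is therefore no added support. The rule also required at least 10 mean CPM in the higher group. Called genes that it left out had larger fitted log2 fold changes, up to 3.19 and down to -6.58. The table of counts does not pair identifiers with names, so the products of these 4 genes are not given.

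The count of called genes depended on the test and on single lines. An unadjusted p under 0.05 was reached by 5926 genes, and over 100 splits of the lines, this one included, the others reached a median of 1322 and at most 5773, the latter with 4 cultivated lines among its 6. DESeq2 called 1279 genes (821 higher and 458 lower in cultivated seeds), and edgeR with upper-quartile scaling called 23 (17 higher and 6 lower). Leaving out df12 raised the count to 32, and leaving out ys16 or ys1 lowered it to 9 in each case. All lines of one group lay above all lines of the other for 345 tested genes, or 1.10%, and 13 of the 14 called genes were among them. Averaged over all splits, chance gives 0.117%. How widely this share varies between splits was not computed, so the excess over that average was not tested. The counts of genes with an unadjusted p under 0.05 differed widely between splits. The call of Glyma.08G012900 was lost on leaving out df14, df17, df36, df3, ys16, ys1, ys23 or ys29, with edgeR adjusted p of 0.055, 0.0537, 0.0621, 0.0535, 0.0792, 0.0789, 0.0523 and 0.0503 in that order. The call of Glyma.11G134300 was lost without df14, df36 or df43 (edgeR adjusted p of 0.0521, 0.062 and 0.0661). With limma voom, Glyma.11G134300 had an adjusted p of 0.18 and Glyma.05G085600 one of 0.144, the highest over all alternatives, where DESeq2 gave the lowest, 5.65e-11 and 1.78e-16.

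Among 11 genes that have been linked to seed or organ size, all of them tested, 3 differed between cultivated and wild seeds when adjusted over the list alone and 0 when adjusted over all genes. By edgeR an unadjusted p under 0.05 was reached by 3 of the 11, beside 5926 of all 31420 tested genes. Adjustment over the list alone does not compare the list with other genes. GmSWEET10a (Glyma.15G049200) and GmSWEET10b (Glyma.08G183500), which encode sugar transporters that supply the embryo from the seed coat, were both higher in cultivated seeds. GmSSS1 (Glyma.19G196000), which encodes a SPINDLY homologue, was lower. These names were attached to identifiers from the literature and could not be checked against an annotation here. P-values over the list alone are over the 14 tested size and domestication genes together, among which the same 3 passed. GmSSS1 stood at 11.9 ± 1.60 CPM in cultivated seeds (SD, n = 6) and 18.7 ± 1.22 CPM in wild seeds (SD, n = 7), a 1.57-fold difference with no overlap between the groups. Its log2 fold change was -0.65 (SE 0.12), with an edgeR adjusted p of 0.000963 over the list alone and of 0.0584 over all genes. GmSWEET10a stood at 128 ± 53.9 CPM in cultivated and 46.0 ± 36.0 CPM in wild seeds, 2.79-fold apart (log2 fold change 1.48, SE 0.491; edgeR adjusted p = 0.0403 over the list alone and 0.156 over all genes). GmSWEET10b was the more abundant of the pair, at 758 ± 293 CPM in cultivated and 392 ± 148 CPM in wild seeds, 1.93-fold apart (log2 fold change 0.95, SE 0.294; edgeR adjusted p = 0.0393 over the list alone and 0.148 over all genes).

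**Figure D1:**
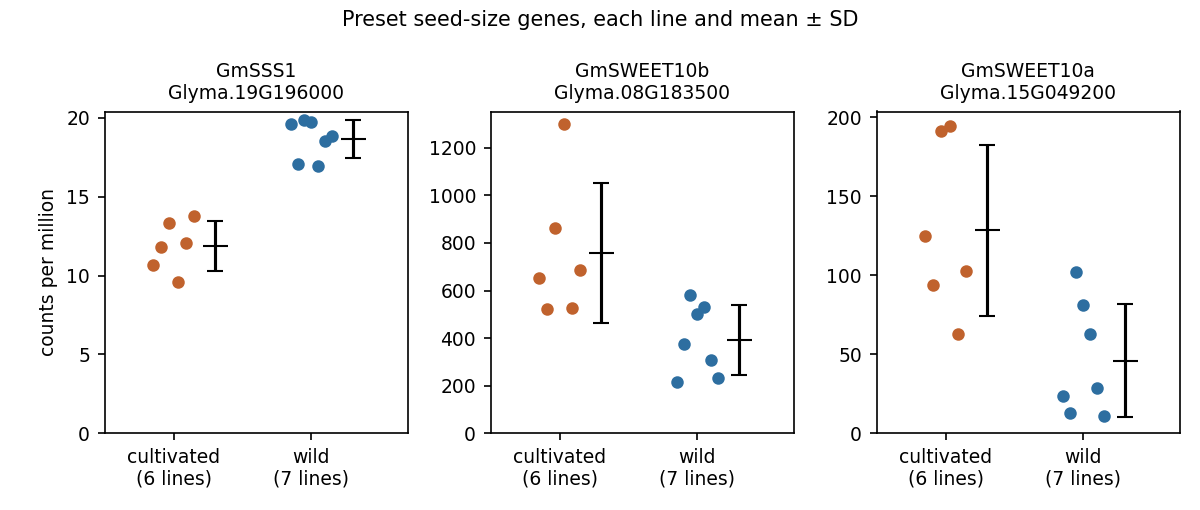
CPM of GmSSS1, GmSWEET10b and GmSWEET10a in each of 6 cultivated lines (orange) and 7 wild lines (blue), with the mean and SD of each group as a bar beside the points. The lines of the groups did not overlap for GmSSS1, with means of 11.9 and 18.7 CPM, and overlapped for both transporter genes.

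The GmSSS1 difference held over the list alone whichever line was left out (edgeR adjusted p of 0.000673 to 0.00377), and it passed over all genes with DESeq2 (adjusted p = 0.000118), 1 surrogate variable (0.036) and the storage protein score in the model (0.0439), within a range of 0.000118 to 0.194 over all alternatives. Over all genes GmSWEET10a and GmSWEET10b passed with DESeq2 only (adjusted p = 0.0418 and 0.0309), and the other alternatives reached up to 0.344 for both. The GmSWEET10a call over the list alone was lost without df12, df17, df36, df43, ys16, ys17, ys29 or ys34 (edgeR adjusted p of 0.0615, 0.075, 0.105, 0.0531, 0.081, 0.0668, 0.0808 and 0.0578 in that order). The GmSWEET10b call was lost without df17, df36, df43, ys16, ys17, ys29 or ys34 (edgeR adjusted p of 0.0567, 0.105, 0.0531, 0.0787, 0.0668, 0.0808 and 0.0578). Limma voom gave both an adjusted p of 0.0568, and leaving out ys29 and ys34 together, a choice made after the data were seen, gave both 0.0931.

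The other 8 genes of the size list did not pass either adjustment. GmCYP78A72 (Glyma.19G240800), a cytochrome P450 gene of a family that promotes organ growth, stood at 217 ± 114 CPM in cultivated and 113 ± 76.3 CPM in wild seeds (log2 fold change 0.94, SE 0.572, edgeR adjusted p = 0.384). POWR1 (Glyma.20G085100), a CCT-domain gene linked to seed protein, oil and weight, stood at 2.61 ± 1.07 and 3.90 ± 0.448 CPM (log2 fold change -0.58, edgeR adjusted p = 0.283). GmST05 (Glyma.05G244100), linked to seed thickness, stood at 109 ± 60.8 and 149 ± 103 CPM. GmOLEO1 (Glyma.20G196600), which encodes an oil body protein and was the 1 measured gene of the oil body list, had a log2 fold change of -1.81 with a standard error of 1.40. It ranged from 0 to 24.8 CPM in cultivated lines and from 0.037 to 73.4 CPM in wild lines, and its log2 fold change was -3.08 without df17, -1.14 without ys26 and -0.041 with the storage protein score in the model, a choice made after the data were seen. GmPP2C-1 (Glyma.17G221100), the 1 gene of the abscisic acid list, had a log2 fold change of -0.17, GmKIX8-1 (Glyma.17G112800) of -0.12 and GmJAG1 (Glyma.20G116200) of 0.36. A CYP78A gene (Glyma.05G019200) was near the lower limit of the tested genes, at 1.16 ± 0.450 CPM in cultivated and 1.84 ± 2.77 CPM in wild seeds. Wild line ys23 held 8.04 CPM of it and the other wild lines 0.296 to 1.56 CPM, and without ys23 its log2 fold change turned from -0.65 to 0.55. Both measured genes of the sugar transport list were the SWEET10 pair, and both passed when adjusted over the list alone.

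The size list as a set had 4 members higher and 7 lower in cultivated seeds by their fitted values. Camera, which compares a list with all other genes, gave an adjusted p of 0.901, and an adjusted p of 0.961 with an estimated correlation. Its direction was up and the mean difference in log2 CPM was 0.20, while the median and mean fitted log2 fold changes were -0.17 and -0.06, so the signs differed. The fry test for changes in either direction gave an adjusted p of 0.000128, and the fry test for a shared direction one of 0.923. Unlike camera, fry does not compare a list with other genes. By edgeR an unadjusted p under 0.05 was reached by 3 of the 11 members and by 5926 of all 31420 tested genes. The result for either direction is therefore not shown to be particular to this list.

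Of 8 domestication genes outside seed size, 3 had enough counts to be tested and none of the 3 passed edgeR over all genes or over the list alone, with 1 at an unadjusted p under 0.05 and 0 called by DESeq2. GmHs1-1 (Glyma.02G269500), linked to the hard seed coat of wild soybean, stood at 3.11 ± 1.13 CPM in cultivated and 1.97 ± 0.523 CPM in wild seeds (log2 fold change 0.66, SE 0.279, edgeR adjusted p = 0.228). The G gene of seed dormancy (Glyma.01G198500) stood at 10.9 ± 1.995 and 10.4 ± 3.89 CPM, and B1 (Glyma.13G241700), which controls the bloom on the seed, at 9.38 ± 2.03 and 7.76 ± 1.05 CPM. SHAT1-5 (Glyma.16G019400), a pod shattering gene, had 6 counts over all 13 lines, and the stem growth gene Dt1 (Glyma.19G194300) had 18. The flowering time gene E1 (Glyma.06G207800) had 0 counts among 229 M, which allows up to 0.0131 CPM of the unscaled total over all lines. Pdh1, the 1 gene of the phenylpropanoid list, and the coat colour gene R were not analysed here.

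Seed storage protein transcripts varied between lines of the same group far more than between the groups. The list held glycinin and β-conglycinin genes, the main reserve proteins of the soybean seed, and 8 of its 10 identifiers were tested. Summed over the 8, storage transcripts ranged from 30.0 CPM in ys34 to 44195 CPM in ys1, a 1475-fold range within the wild lines. Glyma.03G163500, the most abundant member, ranged from 0.930 CPM in df14 to 13987 CPM in df12 among cultivated lines and from 5.26 CPM in ys16 to 11321 CPM in ys1 among wild lines. The score used to place each line, the mean log2 CPM of the 8 members, was 5.34 ± 3.26 in cultivated lines (SD, n = 6) and 5.82 ± 3.69 in wild lines (SD, n = 7; exact permutation test, two-sided p = 0.800). By edgeR none of the 8 members passed over all genes or over the list alone, 1 reached an unadjusted p under 0.05, and DESeq2 called 0 of the 7 for which it gave an adjusted p. That 1 member, Glyma.20G148200, named after its values were seen, rested on df12, as its log2 fold change of 2.30 (edgeR adjusted p = 0.215) was 0.081 without that line (adjusted p = 0.96, the highest over all alternatives, where DESeq2 gave 0.136, the lowest). The fitted values of 2 members were higher and of 6 lower in cultivated seeds, with a median log2 fold change of -0.52 and a mean of -0.25. Camera gave an adjusted p of 0.901, and an adjusted p of 0.961 with an estimated correlation, which was 0.811 between members. Without df14, df36 or ys1 the mean difference of the list in log2 CPM moved from -0.48 to 0.32, 0.05 and 0.21, and leaving out ys29 and ys34 together, chosen after the data were seen, moved it to -2.09 (camera adjusted p = 0.0957, the lowest over all alternatives). Glyma.20G148300 and Glyma.20G148400 differed by at most 1.09% of their counts in all 13 lines, so these 2 members were not independent measurements and the sum holds both.

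**Figure D2:**
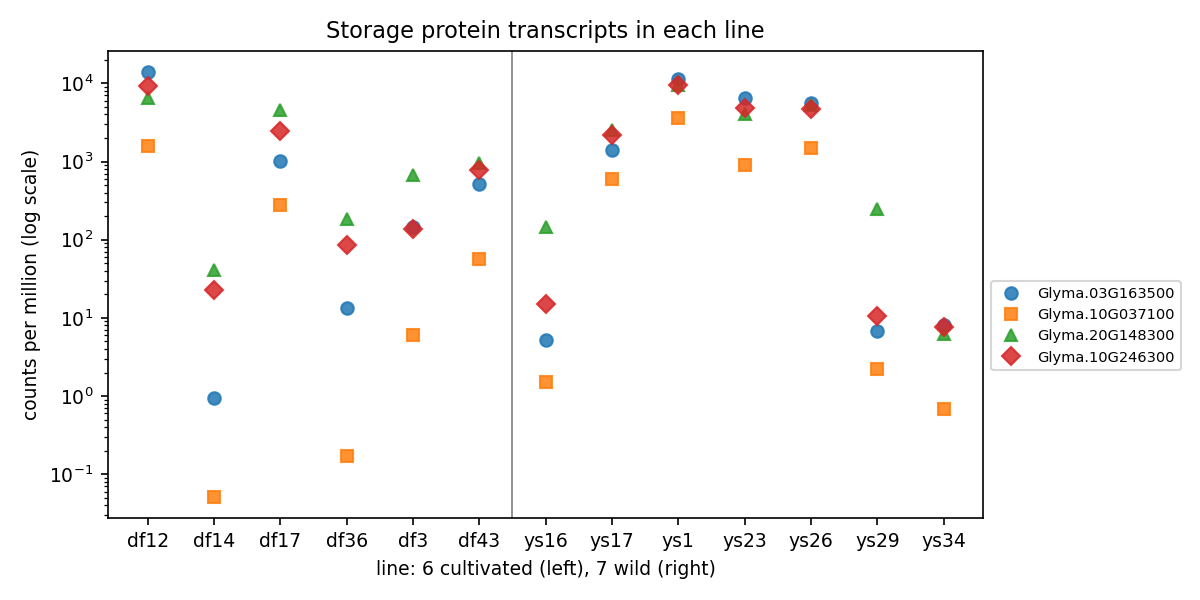
CPM, on a log scale, of 4 storage protein identifiers in each of the 6 cultivated lines (left of the vertical line) and 7 wild lines (right of it). Glyma.03G163500 spans 0.930 to 13987 CPM in cultivated and 5.26 to 11321 CPM in wild lines, and lines low in 1 of the 4 tended to be low in the others.

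Over all tested genes, lines of the same group resembled each other slightly more than lines of different groups. The mean Pearson correlation of log2 CPM was 0.897 between cultivated lines, 0.891 between wild lines and 0.879 between the groups. The excess within groups, 0.0140, was reached by a share of 0.0291 of the 1716 ways to split the lines (exact permutation test, one-sided). It was 0.00793 without df36 (exact one-sided p = 0.121) and 0.0102 without df43 (p = 0.0859, exact), and among genes with a mean log2 CPM of at least 5 it was 0.0246 (p = 0.0921, exact).

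The first principal component, with 24.4% of the variance, did not separate cultivated from wild lines (exact permutation test, two-sided p = 0.522, adjusted p = 0.670 over 3 components), and the second, with 20.4%, did (p = 0.00117, adjusted p = 0.00350, exact). On the second component 3 cultivated lines lay lowest, df36 at -130, df43 at -74.3 and df14 at -50.8. The groups were parted there only narrowly, as cultivated df3 (10.776) and df17 (9.16) lay beside wild ys16 (10.782) and ys26 (12.9). The storage protein score followed the first component (Pearson r = 0.910, permutation p = 5e-05; Spearman rho = 0.929, permutation p = 1e-05, the smallest that 100000 permutations can give; n = 13). Adjusted over 4 relations of the score, these p-values were 0.0002 and 4e-05. Without the 2 lines farthest from the median score r was 0.864, and it was 0.970 within cultivated and 0.940 within wild lines. The score showed no relation past the threshold with the second component (r = 0.246, rho = 0.0714, permutation p = 0.426 and 0.821), with the share of the 8 most abundant features (r = -0.367, rho = -0.220, permutation p = 0.220 and 0.473) or with total counts (r = -0.268, rho = -0.258, permutation p = 0.382 and 0.395).

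**Figure D3:**
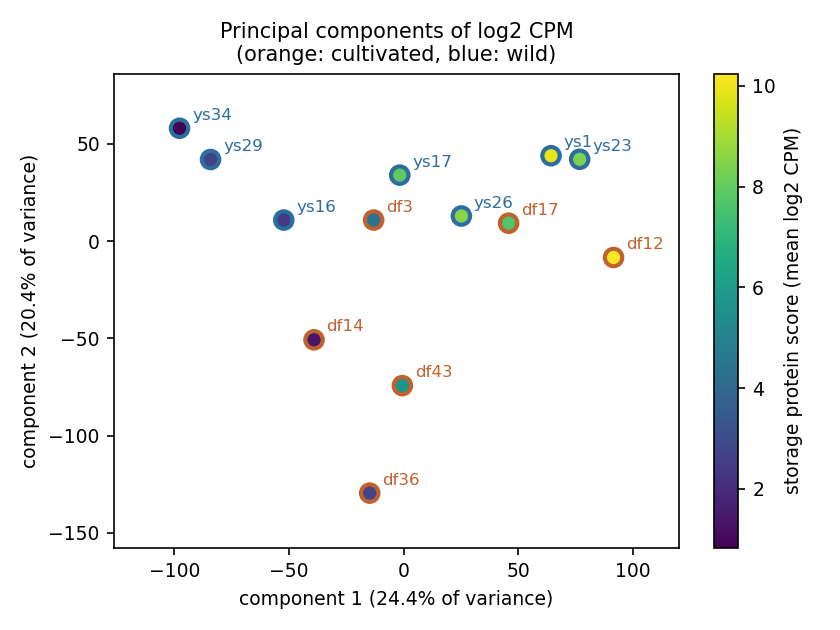
First and second principal components of log2 CPM over 31420 tested genes, with 24.4% and 20.4% of the variance. Each point is 1 of 13 lines, with an orange rim for cultivated and a blue rim for wild, and its fill gives the storage protein score, which rises from left to right along the first component.

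The spread between lines did not differ between the groups beyond chance. Over 17436 genes with a mean log2 CPM of at least 3, the median SD of log2 CPM was 0.389 among cultivated and 0.279 among wild lines, and the median log2 ratio of wild over cultivated SD was -0.36 (exact permutation test, two-sided p = 0.387). No gene had at least 10 counts in every line of one group and 0 in every line of the other, a count of 0 that held with a minimum of 5 or 20 counts.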

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

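In 5 of 70 groups of lines, or 7.14%, the line farthest from the others lay outside the range allowed by Dixon's 95% limit, where chance alone gives about 5%. Of these 5, 2 were in genes whose values are not printed, and without such genes, left out after the first result was seen, the count was 3 of 60. Wild line ys16 had 23.61 M counts, where the other wild lines had 13.9 M to 18.1 M. Glyma.05G085600, lower in cultivated seeds, stood at 1.73 log2 CPM in wild line ys1 and at 4.13 to 4.75 in the other wild lines. Glyma.08G012900, higher in cultivated seeds, stood at -0.0055 log2 CPM in wild line ys34 and at 1.58 to 2.47 in the other wild lines.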

How the results depend on the processing

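The alternatives with the storage protein score, without the 8 most abundant features and without ys29 and ys34 were chosen after seeing the data. The 14 calls (8 higher, 6 lower in cultivated seeds, all at least 2-fold) were all kept with RLE factors, upper-quartile factors, no filter, DESeq2, 1 surrogate variable, the score in the model and without the 8 features. The stricter filter kept 9 of them, limma voom 8 and the fit without ys29 and ys34 10. The counts were 23 (17 higher, 22 at least 2-fold) with upper-quartile factors, 25 (19 higher, 25 at least 2-fold) with no filter, 1279 (821 higher, 458 lower, 508 at least 2-fold) with DESeq2, and 124 (86 higher, 38 lower, 91 at least 2-fold) with 1 surrogate variable. They were 97 (62 higher, 35 lower, 71 at least 2-fold) with the score in the model and 22 (13 higher, 22 at least 2-fold) without ys29 and ys34. Limma voom called 12 genes, 2 of them lower. RLE factors gave 15 calls, the stricter filter 14 and the fit without the 8 features 16. The cause of these differences was not tested. Leaving out 1 line gave 9 to 32 calls, 4 to 21 higher and 4 to 11 lower, with 9 to 32 at least 2-fold. The count of calls higher in cultivated seeds was 21 without df12, 13 without ys26, 5 without df17 or ys17, and 4 without ys16 or ys1, and that of lower calls was 11 without df12.

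Of the 14 tested size and domestication genes 3 passed over the list alone, against 1 with limma voom and 1 without ys29 and ys34, and 1 to 3 when leaving out 1 line. The 0 genes detected in one group only stayed 0 in all alternatives run. The excess similarity within groups, 0.0140, kept its side of the threshold except at a mean log2 CPM of at least 5 (0.0246, exact p = 0.0921) and without df36 or df43, with a leave-one-out range of 0.00793 to 0.0176. The spread ratio kept its sign and stayed past no threshold in all alternatives run, from -0.46 to -0.16 when leaving out 1 line. The cause was not tested for any of these.

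Signs turned only for values past no threshold. With limma voom these were Glyma.05G019200 (0.28), Glyma.20G148400 (3.36e-05) and Glyma.10G246300 (0.26). With the score in the model they were Glyma.20G148400 (0.24), Glyma.20G148300 (0.23) and Glyma.10G246300 (0.78). With 1 surrogate variable it was Glyma.20G146200 (-0.20), and without ys29 and ys34 Glyma.17G112800 (0.17) and Glyma.01G198500 (-0.11). Leaving out 1 line gave -0.83 to 0.55 for Glyma.05G019200, -0.32 to 0.060 for Glyma.17G112800, -0.020 to 0.20 for Glyma.01G198500, -3.39 to 0.21 for Glyma.03G163500, -1.29 to 0.081 for Glyma.20G148400, -1.29 to 0.082 for Glyma.20G148300, -1.62 to 2.34 for Glyma.20G146200, -2.13 to 0.12 for Glyma.10G246300 and -1.46 to 0.32 for the storage list. The cause was not tested.

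No paired analysis was possible because the replicate numbers only name samples and every sample is a different line. Lists were not run with DESeq2, which gives no camera test, or with the score in the model. The depth limits low genes most, as 3 counts stand for up to 0.237 CPM of the unscaled totals.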

Other observations

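The test of the 8 most abundant features on the storage protein score and the test of called genes beside domestication genes were chosen only after the result was seen, as was the storage protein score itself. Beside the storage proteins, 1717 of 31412 other tested genes followed the storage protein score in an edgeR model that also held the group, 1126 rising and 591 falling with it. Permuting the score 40 times gave at most 1 such gene. Among the size and domestication genes, the oleosin gene GmOLEO1 rose with the score by 3.30 log2 units per SD of the score (edgeR adjusted p = 0.00751), GmST05 by 0.73 (adjusted p = 0.0126) and the dormancy gene G by 0.36 (adjusted p = 0.0311). GmSWEET10a had a slope of 0.59 (adjusted p = 0.165) and GmSSS1 of 0.01 (adjusted p = 0.981).

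Storage protein transcripts spanned 9.42 log2 units of the score between lines of the same stage label. A few abundant features taking most counts would lower other genes in the lines where their share is large, but the share of the 8 most abundant, 15.8% to 39.2%, can shift other genes by at most 0.470 log2 units between lines, which argues against that explanation. Lines at different points of seed filling on the day of sampling are a candidate explanation, and 5.47% of the other tested genes followed the score, just above the 5% named before that share was computed, though for a score chosen after the storage values were seen. Any other strong difference between the lines in maturation may give the same share, and seed age or size was not analysed here.

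Few genes were called different between cultivated and wild seeds by edgeR. This does not show that few differed, as 5926 genes reached an unadjusted p under 0.05, against a median of 1322 and at most 5773 over the other splits. Variation in seed filling between lines may hide group differences: with the storage protein score in the model edgeR called 97 genes in place of 14. With 1 surrogate variable in place of the score it called 124, so the rise does not single out seed filling. Of 100 splits of the lines into groups of 6 and 7, 2 gave as many calls as the real one, the real one included, a share under 0.05. Calls of at least 2-fold gave the same share, but this was hardly a second test, as the 2 counts differed only in the split with most calls. Chance is made less likely but not excluded, as only 100 of the 1716 splits were drawn and 1 of them gave far more calls. The highest other split, with 3 cultivated lines among its 6, gave 217 calls (167 at least 2-fold), several times the real count. Its groups differed by 4.63 in the score and it gave 1 call with the score in the model. However, 6 other splits with score differences of 4.11 to 4.90 in either direction gave 0 to 2 calls without it. That difference alone thus does not account for the 217, and their cause was not identified. With the score in the model only the real one (1) of the 100 splits reached 97, a share under 0.05. Chance is again made less likely but not excluded, as the score was chosen after the data were seen. The limit of 100 drawn splits holds here too. The highest other, which differed from the real one by 1 line, gave 28. With DESeq2 only the real one (1) of 40 reached 1279, a share under 0.05 that rests on rank alone. There 2 other splits came close, at 1196 and 1192 calls, with 5 and 4 of the 6 cultivated lines kept together. The other split with 5 in its group of 6 gave 17 calls, and 1 with 5 in its group of 7 gave 0. The others with 4 together, in either group, gave 0 to 99. Such overlap alone thus does not account for the high counts. DESeq2 could thus call nearly as many genes for a grouping other than the real one.

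Camera p-values as small as that of the real split were given by 97 of 100 splits for the storage protein list and by 79 of 100 for the size list, so chance cannot be excluded for either. The camera permutation results over the storage protein list were a real p of 0.901 and a smallest other p of 2.85e-11, and over the size list a real p of 0.851 and a smallest other p of 0.0265. Genes detected in one group only numbered 0, so that no share could be formed to test the alignment of wild reads to the reference. Of 268 genes with an unadjusted edgeR p under 0.001, 64.9% were higher in cultivated seeds. Whether poorer alignment of wild reads adds to this lean, or to the calls higher in cultivated seeds, was not tested.

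Genes with an unadjusted p under 0.001 numbered 268, 174 of them higher in cultivated seeds, and 14.9% had another such gene within 10 identifiers on the same chromosome. Random draws of as many tested genes gave a median of 11.6% and a 95th percentile of 16.4% (permutation p = 0.137, 10000 draws), and as many genes with the smallest p for the storage protein score, chosen without regard to group differences, gave 13.8% (permutation p = 0.237). Neither share passed, so the test leaves open whether haplotypes shared by the lines of a group may add to the first. Reads wholly shared between near-identical neighbours would give near-equal counts. Of 21 neighbouring pairs, 0 (0%) had counts within 5% of each other in at least 10 lines, which argues against wholly shared reads for these pairs. Such counts were rare in general, at 1 of 10953 adjacent pairs with a mean count of at least 100. Reads shared in part need not give near-equal counts and were not tested. The called gene Glyma.02G270400 lies 7 identifiers from the hard seed gene GmHs1-1, and 11.1% of random draws placed as many called genes within 10 identifiers of a size or domestication gene, so a linked haplotype cannot be told apart from chance placement here.

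The most abundant feature, Glyma.U005800, singled out after its values were seen, took 11.1% of counts on average. For 9 features every line had either 0 counts or at least 100, with the zeros in cultivated lines only for 3 features, in wild lines only for 5 and in both for 1. No chromosome held more or fewer genes with p under 0.001 than the rest after adjustment (lowest Fisher's exact adjusted p = 0.234).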
